A study of Mus musculus with 17 samples.

How the data were processed

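The series compares livers of C57BL/6 mice on a high-fat diet, liver-specific knockout (LKO) against flox/flox control. RNA-seq covered 2 control and 3 LKO samples and ATAC-seq 6 and 6. The design text calls the ATAC samples biological replicates. For the RNA samples it does not say that they came from separate animals, so their p-values measure only the spread between these samples. Per the labels' protocols, RNA was total RNA from TRIzol, read as single 50-base reads on a BGI 500 instrument. For ATAC-seq, 50000 nuclei isolated from frozen liver went into each transposase reaction, read in pairs of 50 bases on a NovaSeq 6000. The submitters' processing notes name the mm10 build, FastQC, BWA 0.7.17-r1188, STAR, Picard 2.8.14, SAMtools, MACS2 2.1.1.20160309, bedtools 2.27.1, HTSeq, HOMER and DESeq2 1.20.0, without saying which step used which. Whether ATAC reads were shifted for the transposase offset, whether peaks were called per sample or on pooled reads, and the annotation version are not given in the sources used here.

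The deposited tables hold a normalized signal per library, which is a count of reads per gene or per peak divided by a size factor per library. Every value is a whole multiple of the library's smallest value within 0.001 (100% of values), so the reads behind each value were recovered by division. In the ATAC libraries LKO12 and LKO2 this step lies so near 1 that low values alone could not tell it from rounding. The tables also hold the authors' log2 fold change, p-value and adjusted p per row, per the file headers; values taken from these are named as from the authors' deposited table. There were 15937 genes for RNA and 159578 peaks for ATAC, on 19 chromosomes, with 0 peaks on X or Y. ATAC rows carry a gene name given by the authors, whose assigning tool is not given in the sources used here. Names that a spreadsheet had turned into dates (22 RNA genes and 251 peaks) and 36 blank names were left unnamed. The recovered reads per library were 19.8 and 19.8 M (mega) in the RNA controls and 19.95, 18.5 and 19.1 M in LKO 1, 2 and 3. They were 59.8, 33.7, 43.2, 35.9, 51.4 and 36.3 M in ATAC controls ctrl10, ctrl15, ctrl16, ctrl4, ctrl7 and ctrl9, and 37.1, 35.8, 68.6, 37.2, 26.0 and 21.2 M in LKO11, LKO12, LKO13, LKO2, LKO3 and LKO5. No 2 libraries held identical values. RNA columns were matched to samples by name; 8 of the 12 ATAC columns carry numbers that do not occur in the sample titles of their group (all but ctrl4, LKO2, LKO3 and LKO5), so the ATAC columns were matched to groups only.

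The design fixed before the data were examined asks for limma on log2(value + 1) where values are normalized, so limma 3.58.1 (R 4.3.3) was fitted to LKO minus control with no covariate, with Benjamini-Hochberg adjusted p under 0.05. That design left open the mean-variance trend in limma's moderation and the minimum mean. Fits with the trend, without it, and with the trend and a mean normalized count of at least 10 were run together, and the trend and the minimum were chosen with their counts of calls in view (RNA: 32 with the trend, 0 without, 30 with the trend and the minimum; ATAC: 5 in each). They left 13242 genes and 159566 peaks. Prior degrees of freedom were 4.53 in RNA (residual 3) and 7.83 in ATAC (residual 10). In all, 17 RNA and 31 ATAC fits or sources of calls were compared, besides other thresholds, among them edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other filters, pseudocounts and scalings, each library left out, and ATAC fits with a covariate. DESeq2 on the recovered RNA reads gave the authors' RNA fold changes again. For ATAC, DESeq2 fold changes from the groups alone had a Pearson's r of 0.843 with the authors' across peaks and 0.997 with log2 total normalized signal as a covariate; this is a hint from the values, and no label states such a term.

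Gene lists (36, fixed before the data were examined, 10 of them markers of cell types) were tested in RNA with camera at a preset correlation of 0.01, with an estimated correlation and with fry. In ATAC a list's median log2 fold change at gene ends was set against 10000 random lists matched on mean accessibility. The plan named transcription start sites, but the gene table used here gives no strand, so peaks within 1 kb of either annotated end of their assigned gene were used. Gene positions are those of RefSeq for GRCm38.p6, the assembly behind mm10; 99.4% of RNA names matched. Expression and gene-end accessibility were compared by Spearman's rho and Pearson's r with 100000 permutations (10000 in the alternatives), two-sided, and calls by Fisher's exact test, two-sided, with peaks within 100 kb of their assigned gene. The background was the genes tested in RNA with at least 1 tested peak.

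Genes named in the text follow a rule fixed before the data were examined: Hnrnpu and Ntrk2; the 12 largest positive and 12 largest negative log2 fold changes among called genes with a mean of at least 50; up to 4 members per list with the smallest adjusted p, where the list has a called member; the 5 peaks with the smallest p in each direction; and for each named gene its assigned peak with the smallest p. Genes named outside the rule are said to be so.

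The tests were checked on simulated data made from the real means, size factors and dispersions, with 50 features changed at each fold. In the RNA simulation over 13242 genes limma called 30%, 64%, 94% and 100% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold. In the ATAC simulation over 159566 peaks it called 4%, 40%, 88% and 100%. Unchanged features made up 6.75% of RNA calls and 4.13% of ATAC calls. In RNA a shifted list of 25 genes gave a camera p of 5.4e-27 and an unshifted list 0.713. Genes were simulated independently, so this check does not cover correlation between the genes of a list, on which the list results below turn. Peaks were simulated independently too, without differences between libraries that many peaks share. The simulated ATAC rates therefore need not hold for these libraries, where a grouping other than the genotype gave 5068 limma calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.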

Results

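Whole livers of C57BL/6 mice on a high-fat diet (HFD) were profiled by RNA-seq and by ATAC-seq, which reads chromatin accessibility from where a transposase inserts into nuclei. Livers with a liver-specific knockout (LKO) were set against livers of flox/flox controls. The column headers name the targeted gene as Hnrnpu, which encodes the nuclear matrix and RNA-binding protein hnRNPU. RNA-seq covered 2 control and 3 LKO samples, and ATAC-seq 6 and 6 biological replicates. The RNA libraries held 18.5 to 19.95 M (mega) reads on genes. The ATAC libraries were less even, with 21.2 to 68.6 M reads in peaks. The comparison asks how loss of hnRNPU in the liver alters transcription and chromatin in a study of liver injury in steatohepatitis (NASH). Values below are normalized counts, given as mean ± SD, and log2 fold changes are LKO minus control on the log2(normalized count + 1) scale, which understates changes of low genes.

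The targeted gene read slightly lower in whole-liver RNA of LKO livers, a difference not past the threshold. Hnrnpu (chromosome 1, 178321108 to 178338891, GRCm38) measured 3356 ± 51.5 in controls (SD, n = 2) and 2877 ± 134 in LKO livers (SD, n = 3), a log2 fold change of -0.22 (SE 0.08) that did not pass limma's threshold (adjusted p = 0.223). The authors' deposited table gives -0.22 with an adjusted p of 0.262. The 3 LKO libraries, at 2823, 2780 and 3029, all lay below the controls at 3393 and 3320. The counts are summed over the gene, and which exons were deleted is not given in the sources used here, so the gene-level value cannot measure loss of the protein. Ntrk2 (chromosome 13, 58806472 to 59133970), which encodes the neurotrophin receptor TrkB, measured 842 ± 185 in controls (SD, n = 2) and 1548 ± 144 in LKO livers (SD, n = 3). Its log2 fold change of 0.89 (SE 0.14) missed the limma threshold (adjusted p = 0.0603), while the authors' deposited table gives 0.88 with an adjusted p of 2.75e-05. All 3 LKO libraries lay above both controls for Ntrk2, and without control 1 its log2 fold change of 1.12 passed in limma (adjusted p = 0.0486), the other libraries left out giving adjusted p-values from 0.0671 (LKO 1) to 0.193 (control 2).

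Among called genes with a mean of at least 50, the largest RNA increases in LKO livers on the log2(normalized count + 1) scale were those of Sult1e1, the estrogen sulfotransferase gene, and Lrtm2, which encodes a leucine-rich repeat membrane protein. Of 13242 genes tested, 30 passed, 20 higher and 10 lower, and all 30 are also called in the authors' deposited table, which calls 410 genes (254 higher, 156 lower). Sult1e1 (chromosome 5, 87575968 to 87591611) went from 13.0 ± 10.46 to 707 ± 175, a log2 fold change of 5.87 (SE 0.45, adjusted p = 0.00951, limma). Lrtm2 (chromosome 6, 119315133 to 119332270) went from 9.14 ± 6.31 to 432 ± 166, a log2 fold change of 5.51 (SE 0.43, adjusted p = 0.00951). Marco, a scavenger receptor of macrophages, rose from 36.7 ± 3.02 to 306 ± 84.1 (log2 fold change 2.99, SE 0.23, adjusted p = 0.00951). Lrit1 (3.65) and Fam25c (3.45) also rose from mean counts under 20 in controls. Smaller increases were seen in Apol9a (1.79), the acute phase gene Orm3 (1.62), the guanylate-binding protein gene Gbp10 (1.44), Hsf2bp (1.44), Vsig10l (1.31), Ly6e (1.23) and the cap-binding protein gene Eif4e3 (1.17), all as log2 fold changes. Ly6e was the most abundant of them, at 10445 ± 1388 in controls and 24558 ± 3968 in LKO livers. Sds, which encodes serine dehydratase, rose from 3213 ± 363 to 5364 ± 66.2 (log2 fold change 0.74, adjusted p = 0.0353).

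Among the genes that fell, Gpc1, a glypican, dropped from 1203 ± 56.2 in controls (SD, n = 2) to 453 ± 115 in LKO livers (SD, n = 3), a log2 fold change of -1.43 (SE 0.18, adjusted p = 0.0413, limma). Prex2, a guanine nucleotide exchange factor for Rac, dropped from 403 ± 34.2 to 170 ± 22.9 (log2 fold change -1.25, SE 0.14, adjusted p = 0.0260). The other genes that fell were B430212C06Rik (-1.74), the beta-3 adrenergic receptor gene Adrb3 (-1.49), the fatty acid hydroxylase gene Cyp4a32 (-1.18), Plekhb1 (-0.997), the vesicular glutamate transporter gene Slc17a8 (-0.88), Cntnap1 (-0.80), Serpina7, the thyroxine-binding globulin gene (-0.63), and Pex11a, a peroxisome membrane protein gene (-0.61). In each of the 23 called genes named here, all LKO libraries lay on the same side of both controls, an arrangement that chance gives in 20% of genes with 2 against 3 libraries; these genes were picked by the test on the same values. Reads of 50 bases may be split between near-identical copies, so the values of Apol9a, Orm3, Gbp10, Cyp4a32 and Ly6e are uncertain. The span of Lrtm2 overlaps that of Cacna2d4 (log2 fold change 3.27, adjusted p = 0.0652), Lrit1 overlaps Lrit2 (0 in both controls and a mean of 27.4 in LKO livers, adjusted p = 0.0268) and B430212C06Rik overlaps Cidea (-2.24, adjusted p = 0.0603); these partners were looked at only after the calls were seen. Counting by strand is not given in the sources used here, so such partners could not be separated. The number of calls rested on single libraries, with 3 without control 2, 1 without LKO 2 and 50 without LKO 1. Without control 2 the calls were Sult1e1, Lrtm2 and Fam25c, while Marco had an adjusted p of 0.0529; without LKO 2 the call was Marco, while Sult1e1, Lrtm2 and Fam25c each had an adjusted p of 0.0807. No named gene passed with each of the 5 libraries left out in turn. It also rested on the variance model, since limma without a mean-variance trend called 0 genes (1972 at unadjusted p under 0.05) and edgeR called 23.

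**Figure D1:**
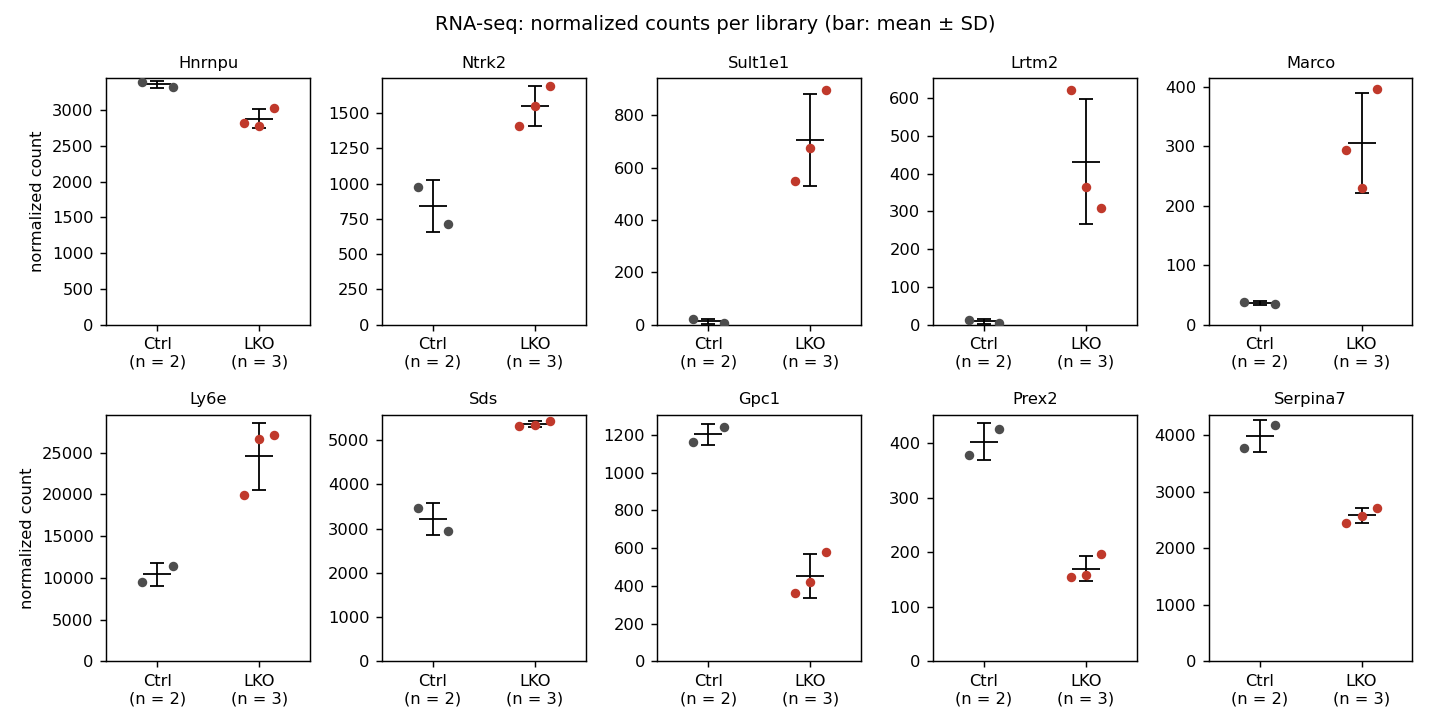
Normalized RNA-seq counts per library (y axis) for 10 genes in control (n = 2) and LKO (n = 3) livers, each point a library and each bar the mean ± SD. The LKO libraries lie above both controls for Ntrk2, Sult1e1, Lrtm2, Marco, Ly6e and Sds and below both for Hnrnpu, Gpc1, Prex2 and Serpina7; the fold change of Hnrnpu (adjusted p = 0.223) and that of Ntrk2 (adjusted p = 0.0603) did not pass the limma threshold.

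Immune gene groups were shifted upward in LKO liver RNA. Of the 36 gene lists fixed beforehand, 13 were shifted by camera with a preset correlation of 0.01, 9 higher and 4 lower, and none held with an estimated correlation, so each shift below rests on the preset value. All 23 measured interferon-stimulated genes had a positive log2 fold change, with a median of 1.15 (adjusted p = 3.23e-15; adjusted p = 0.595 with an estimated correlation). None of the 23 passed over all genes, 19 passed when adjusted over the list alone, and the authors' deposited table calls 16 of them higher. Markers of macrophages and Kupffer cells had a median of 0.54, with 20 of 22 positive (adjusted p = 4.96e-10; adjusted p = 0.595 with an estimated correlation). Marco was the called member over all genes, and 14 higher and 1 lower passed when adjusted over the list alone. Cd5l (log2 fold change 0.74), Cd68 (0.70) and Mpeg1 (0.66) each had an adjusted p of 0.0603. The lipid-associated macrophage list had a median of 0.54 over 16 genes (adjusted p = 2.12e-07; 0.595 as adjusted p with an estimated correlation), with 0 past the threshold over all genes and 7 when adjusted over the list alone. Neutrophil markers had the highest median, 1.91 over 12 genes, none past the threshold over all genes and 8 when adjusted over the list alone (adjusted p = 4.67e-06; adjusted p = 0.595 with an estimated correlation). The neutrophil marker S100a8, chosen after its values were seen, read 69.3, 76.0 and 368 in LKO 1, 2 and 3, against 11.7 and 48.6 in the controls. Chemokines and inflammatory cytokines had a median of 0.28 over 26 genes (adjusted p = 0.000238; adjusted p = 0.595 with an estimated correlation), with 0 past the threshold and 4 when adjusted over the list alone. Apoptosis genes had a median of 0.17 over 18 genes (adjusted p = 0.00441; adjusted p = 0.595 with an estimated correlation), with 0 past the threshold and 2 when adjusted over the list alone.

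Liver-made secretory and amino acid genes also shifted upward, and lipid genes downward. The acute phase and complement list had a median log2 fold change of 0.46 with 26 of 27 positive (adjusted p = 2.18e-08; adjusted p = 0.595 with an estimated correlation); Orm3 passed over all genes and 7 passed when adjusted over the list alone. C9 (0.61, adjusted p = 0.0603), Orm2 (2.25, adjusted p = 0.0823) and Lbp (0.46, adjusted p = 0.115) did not pass. The amino acid and urea cycle list had a median of 0.20 with 29 of 31 positive (adjusted p = 1.93e-07; adjusted p = 0.595 with an estimated correlation), Sds past the threshold and 7 when adjusted over the list alone. Its members Bhmt (0.62, adjusted p = 0.0975), Agxt (0.34, adjusted p = 0.118) and Tat, the tyrosine aminotransferase gene (0.95, adjusted p = 0.124), did not pass. Hepatocyte identity genes had a median of 0.17 over 25 genes (adjusted p = 0.0147; adjusted p = 0.609 with an estimated correlation), 0 of them past the threshold by either adjustment.

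Fatty acid oxidation and PPARA target genes were negative in 30 of 33, with a median of -0.21 (adjusted p = 7.12e-06; adjusted p = 0.609 with an estimated correlation) and 0 past the threshold by either adjustment. De novo lipogenesis had a median of -0.42 over 22 genes (adjusted p = 0.000468; adjusted p = 0.609 with an estimated correlation), 0 past the threshold and 4 lower when adjusted over the list alone. Cholesterol synthesis had a median of -0.20 over 24 genes (adjusted p = 0.00534; adjusted p = 0.759 with an estimated correlation), 0 past the threshold and 1 lower when adjusted over the list alone. Sinusoidal endothelial markers were negative in 16 of 17 (median -0.18, adjusted p = 0.00383; adjusted p = 0.595 with an estimated correlation), 0 past the threshold by either adjustment. In fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, the lowest adjusted p was 0.283. Fry's mixed test, which asks for change in either direction, passed for apoptosis (adjusted p = 0.00311), gluconeogenesis (0.0180), hepatic stellate cells (0.0316) and xenobiotic metabolism (0.0430). Leaving out single libraries ended the shift of cholesterol synthesis (adjusted p = 0.675 without control 1, 0.308 without LKO 1), de novo lipogenesis (0.144 without control 1), endothelial markers (0.114 without LKO 1) and hepatocyte identity (0.0871 without LKO 3), all as camera adjusted p-values.

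**Figure D2:**
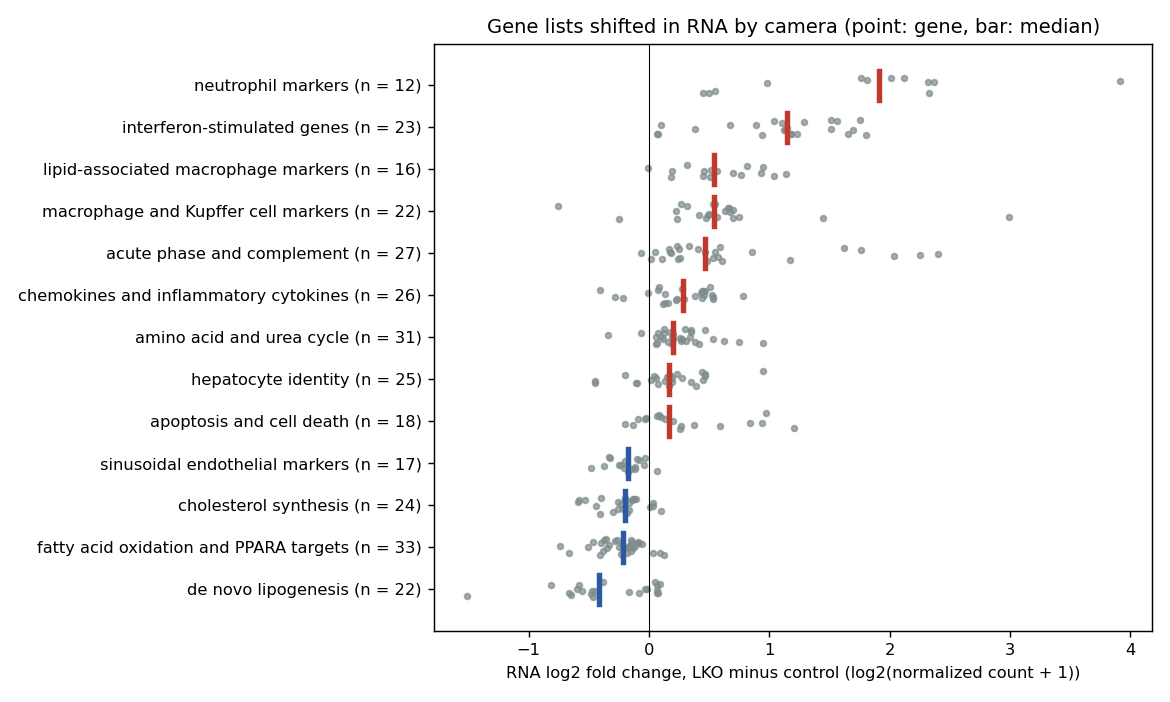
RNA log2 fold change, LKO minus control (x axis, log2(normalized count + 1) scale), of every measured gene (points) in the 13 lists shifted by camera with the preset correlation, with each list's median as a bar. Neutrophil markers have the highest median, 1.91, and de novo lipogenesis the lowest, -0.42; none of the shifts held with an estimated correlation.

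The other 23 lists were not shifted by camera, with adjusted p-values between 0.0572 and 0.962. NRF2 targets and glutathione genes had a median log2 fold change of 0.13 (adjusted p = 0.0572). Adjusted p was 0.0884 for lipid droplet genes, xenobiotic metabolism and cholangiocyte markers, 0.104 for neurotrophin receptors and ligands, 0.147 for chromatin architecture factors and 0.169 for female-high liver genes. It was 0.173 for ATF4 targets, 0.198 for the unfolded protein response, 0.217 for fetal liver genes, 0.274 for T and NK cell markers, 0.348 for extracellular matrix and fibrosis, 0.411 for p53 targets, 0.503 for B and plasma cell markers and 0.572 for proliferation. Bile acid synthesis and the circadian clock were at 0.693. Gluconeogenesis, hepatic stellate cells, red blood cells and the hnRNP family were at 0.815, male-high liver genes at 0.944 and oxidative phosphorylation at 0.962. Several of these lists passed by camera with a single library left out. Without control 1 they were NRF2 targets (adjusted p = 2.83e-05), the unfolded protein response (lower, 0.000288) and xenobiotic metabolism (0.00331). Without control 2 they were T and NK cell markers (0.00139), extracellular matrix (0.00486), cholangiocyte markers (0.0334), lipid droplet genes (lower, 0.0336) and neurotrophin receptors and ligands (0.0368), while NRF2 targets turned negative (0.871). Without LKO 2 lipid droplet genes (0.0236) and female-high genes (0.0321) were lower, and without LKO 3 NRF2 targets (0.00021) and cholangiocyte markers (0.00187) were higher and the unfolded protein response lower (0.00221). With only genes of a mean of at least 50, cholangiocyte markers (0.00713), NRF2 targets (0.0280) and xenobiotic metabolism (0.0382) were higher.

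In the gluconeogenesis list, Sds rose while the log2 fold changes of Pklr (-0.58, adjusted p = 0.0572), Got1 (0.61, adjusted p = 0.0730) and Pcx (-0.42, adjusted p = 0.113) did not pass. The median and the mean of this list differ in sign, at -0.09 and 0.03; the same holds for the circadian clock (-0.14 and 0.02), for stellate cells (0.04 and -0.01), for male-high genes (-0.03 and 0.01) and for oxidative phosphorylation (0.004 and -0.002).

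Accessibility rose at Lrtm2 and fell at Dmrta1 in LKO livers. Of 159566 peaks tested, 5 passed the limma threshold, 3 higher and 2 lower, and 9790 had an unadjusted p under 0.05. The peak on chromosome 6 from 119329222 to 119330896, inside Lrtm2, went from 134 ± 29.4 in controls to 420 ± 87.9 in LKO livers (SD, n = 6 each; log2 fold change 1.64, SE 0.17, adjusted p = 0.00325). A shorter peak inside the same gene, from 119326923 to 119327178, went from 19.2 ± 7.61 to 91.2 ± 31.4 (log2 fold change 2.19, adjusted p = 0.0120). Both peaks also lie within the annotated span of Cacna2d4 (119236524 to 119352407), so they cannot be credited to Lrtm2 alone. The peak from 118939434 to 118940322 on the same chromosome, 53.9 kb outside its assigned gene 4931430N09Rik, had a log2 fold change of 1.63 (adjusted p = 0.0120). The peak on chromosome 4 from 89687827 to 89689302, at an annotated end of Dmrta1, a transcription factor gene, fell from 597 ± 194 to 169 ± 31.7 (log2 fold change -1.77, SE 0.20, adjusted p = 0.00475). The peak from 151414903 to 151416121 on chromosome 4, 323 kb outside Gm13090, fell from 618 ± 309 to 130 ± 59.8 (log2 fold change -2.22, adjusted p = 0.0134).

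With each of the 12 libraries left out in turn the number of called peaks lay between 2 (without ctrl15) and 10 (without LKO13), with 8 without ctrl10 and 3 without LKO11. The Dmrta1 peak and the longer Lrtm2 peak passed in all 12 of these fits. The shorter Lrtm2 peak did not pass without ctrl15 (adjusted p = 0.0594), LKO11 (0.0807) or LKO2 (0.0525), the peak assigned to 4931430N09Rik without ctrl15 (0.0594) or LKO2 (0.0525), and the Gm13090 peak without ctrl15 (0.0662), ctrl7 (0.0709), LKO11 (0.0807) or LKO5 (0.0655).

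The next peaks in rank did not pass. They were a peak assigned to Hoxc4 on chromosome 15, 103058703 to 103061748 (log2 fold change 1.52, adjusted p = 0.125), and a peak inside Rab11fip3 on chromosome 17, 26003445 to 26005520 (1.03, adjusted p = 0.187). On the lower side they were a second Gm13090 peak on chromosome 4, 151418415 to 151418949 (-1.88, adjusted p = 0.0825), a peak assigned to 1700030C10Rik on chromosome 12, 20614600 to 20615599 (-1.28, adjusted p = 0.0900), and a peak assigned to Gatsl2 on chromosome 5, 133487655 to 133489436 (-1.08, adjusted p = 0.0900). Of the 36 named RNA genes with an assigned peak, only Lrtm2 had a peak past the threshold. The peaks with the smallest p at Prex2 (-1.01, adjusted p = 0.0900), Gpc1 (-0.997, adjusted p = 0.187), Cyp4a32 (-1.91, adjusted p = 0.225) and Adrb3 (-0.69, adjusted p = 0.643) did not pass. At Hnrnpu the peak from 178329777 to 178330759 had a log2 fold change of -1.05 (adjusted p = 0.766), with ctrl10 far above the other controls at 856, and of -0.72 with total signal as a covariate (adjusted p = 0.107). The authors' deposited table calls this Hnrnpu peak lower (-0.72, adjusted p = 0.00161). At Ntrk2 the peak from 58896230 to 58898116, inside the gene, went from 174 ± 63.9 to 375 ± 102 (log2 fold change 1.12, adjusted p = 0.355). The authors' deposited table calls this Ntrk2 peak higher (1.19, adjusted p = 5.69e-06).

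The count of peaks depended on how the libraries' total signal was treated. The total normalized signal was 52.9 M in control ctrl10 and 46.6 M in LKO13, against 33.4 to 40.4 M in the other 10 libraries; group means were 40.2 ± 6.49 M and 37.5 ± 4.77 M (SD, n = 6 each; exact permutation test, two-sided, p = 0.461). With total signal as a covariate, chosen after seeing the data, limma called 58 peaks (16 higher, 42 lower), the 5 above among them. Peaks at Prex2 (adjusted p = 0.000286), Gpc1 (0.00357), Cyp4a32 (0.00514) and Ntrk2 (0.0218) then passed. The authors' deposited table calls 1427 peaks, 367 higher and 1060 lower, including 4 of the 5. A DESeq2 fit of the groups alone called 161 (29 higher, 132 lower).

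**Figure D3:**
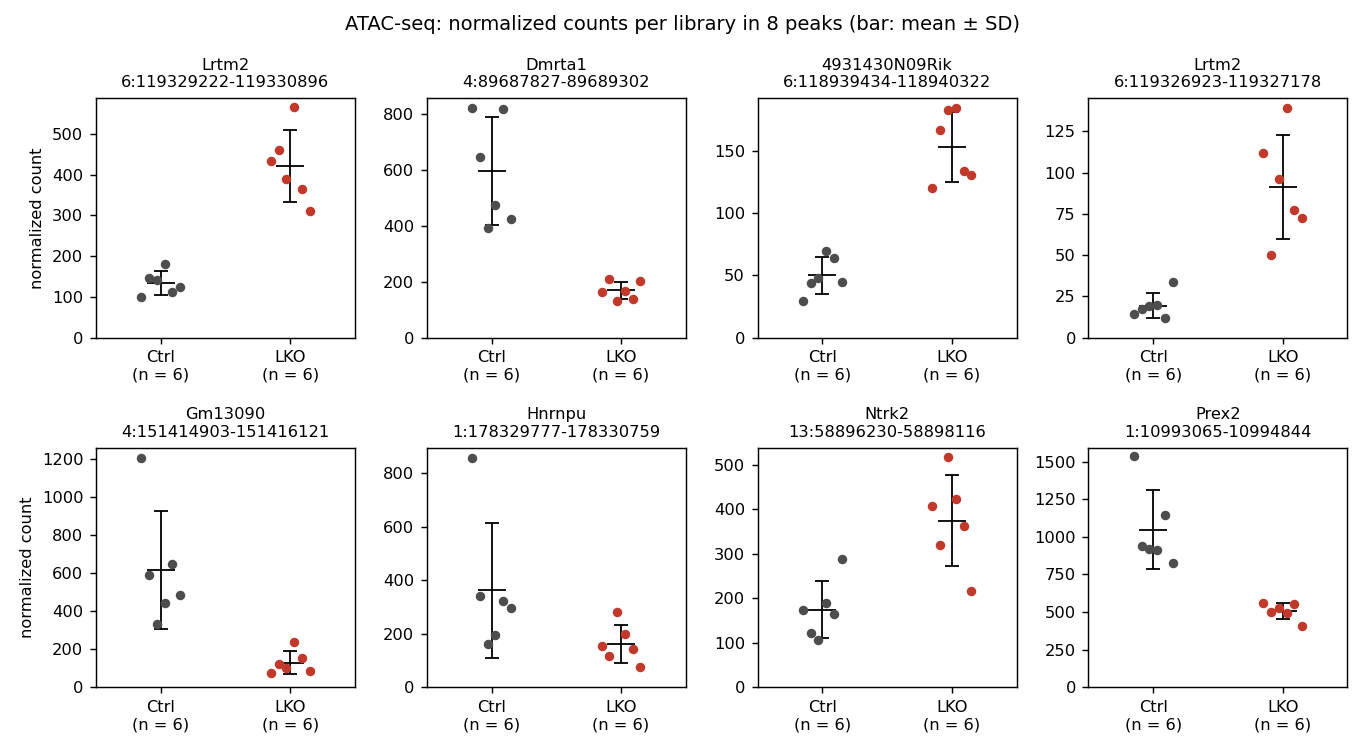
Normalized ATAC-seq counts per library (y axis) in control (n = 6) and LKO (n = 6) livers at the 5 peaks past the limma threshold and at the peak with the smallest p of Hnrnpu, Ntrk2 and Prex2, each point a library and each bar the mean ± SD; coordinates are chromosome and position in GRCm38. The LKO libraries lie apart from the controls in the 5 called peaks and at Prex2, and overlap them at Hnrnpu (adjusted p = 0.766) and Ntrk2 (adjusted p = 0.355).

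Accessibility at gene ends was shifted for 11 lists against 10000 matched random lists. Median log2 fold changes were higher than the random median for interferon-stimulated genes (0.07 against -0.09) and the amino acid and urea cycle (-0.01 against -0.13). They were lower for sinusoidal endothelial markers (-0.35 against -0.08), xenobiotic metabolism (-0.31 against -0.08), fatty acid oxidation and PPARA targets (-0.29 against -0.13), male-high liver genes (-0.28 against -0.10), hepatocyte identity (-0.26 against -0.14), bile acid synthesis (-0.26 against -0.12), and acute phase and complement (-0.23 against -0.12). The adjusted p was 0.000778 for each of these. Lipid droplet genes (-0.22 against -0.13, adjusted p = 0.00318) and ATF4 targets (-0.20 against -0.11, adjusted p = 0.00140) were lower too. Random lists ignore correlation between genes, and 53 of 100 splits of the 12 libraries gave at least as many shifted lists, so chance was not excluded for their number. The other 24 lists tested had adjusted p-values from 0.0974 to 0.923, and red blood cell markers had too few genes. Without ctrl10 the shifted lists numbered 5. With total signal as a covariate 9 lists were shifted, 5 of them among the 11. Those 5 were interferon-stimulated genes, amino acid and urea cycle, fatty acid oxidation, lipid droplet and endothelial markers, the same lists as without ctrl10.

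Across genes, RNA and gene-end accessibility moved in the same direction more often than not. Over 10938 genes the log2 fold changes had a Spearman's rho of 0.227 (permutation p = 1e-05, the smallest that 100000 resamples give) and a Pearson's r of 0.318 (permutation p = 1e-05), with the same sign in 56.7% of genes. Genes are not independent replicates. Among the 21 genes past the RNA threshold with a gene-end peak, rho was 0.684 (permutation p = 0.001). Of genes called higher in RNA, Lrtm2 also had a called peak that was higher (1 of 19, against 0.00153 expected, Fisher's exact test, two-sided, p = 0.00153); without LKO 2 in the RNA fit Lrtm2 was not called and the overlap was 0. No gene called lower had a called lower peak (0 of 9, against 0.000726 expected). Only 1 gene of the background, Dmrta1, had a called lower peak, so this count could hardly have come out otherwise. Without LKO 3 in the RNA fit Dmrta1 was called lower in RNA too. With the calls of the authors' deposited table, 23 of 236 higher genes had a higher peak (3.83 expected, Fisher's exact p = 4.64e-12). In the authors' deposited table these included Lrtm2, Ntrk2, Apol9a, Hsf2bp, Orm2, Tat and Got1. Of 147 lower genes in the authors' deposited table, 22 had a lower peak (6.27 expected, Fisher's exact p = 2.61e-07), among them Dmrta1, Prex2, Gpc1, Adrb3 and Cyp4a32. Opposite directions met in 7 of the higher genes of the authors' deposited table (10.1 expected, Fisher's exact p = 0.415) and 0 of the lower (2.38 expected, Fisher's exact p = 0.180).

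Called peaks were too few to place. Of the 3 higher peaks 0, and of the 2 lower peaks 1, lay within 1 kb of an annotated gene end, against 19.2% of uncalled peaks (Fisher's exact test, p = 1 and p = 0.348). By the authors' deposited table, gene ends held 76 of 367 higher peaks (20.7%, Fisher's exact p = 0.196) and 229 of 1060 lower peaks (21.6%, p = 0.127). The share was 23.6% of the 108649 peaks they did not call, counting only peaks they gave an adjusted p. With total signal as a covariate the share among 42 lower peaks was 33.3% (Fisher's exact p = 0.0294).

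**Figure D4:**
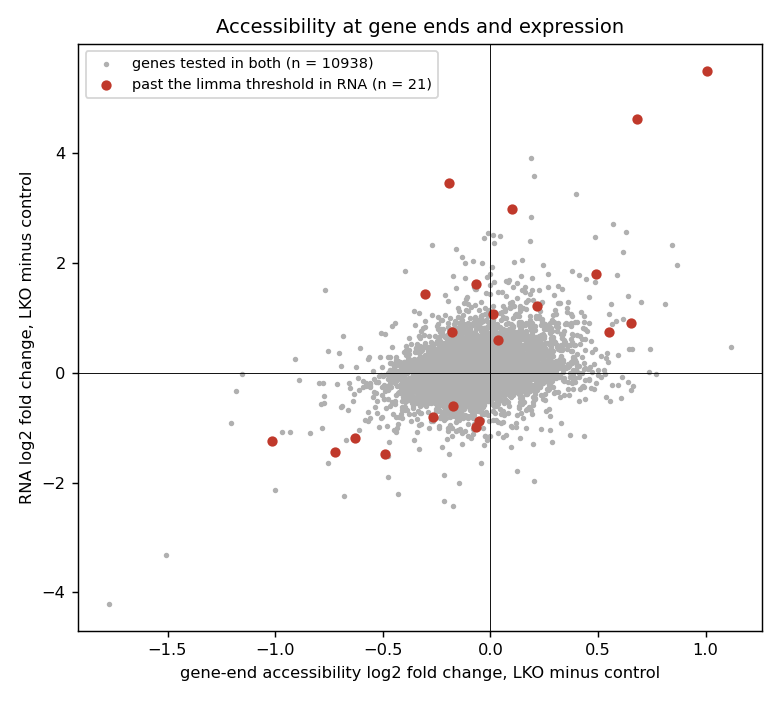
RNA log2 fold change (y axis) against the mean log2 fold change of ATAC peaks within 1 kb of the gene's ends (x axis), both LKO minus control, for 10938 genes, with the 21 past the limma threshold in RNA in red. Points lean toward the diagonal (rho 0.227 over all genes, 0.684 over the 21).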

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

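The tests of fewer hepatocytes, of the interferon against the macrophage medians of rho with the signal covariate and of the macrophage gene ends with that covariate were chosen only after the result was seen. In 94 groups of 6 ATAC libraries, 16 had a highest or lowest library far from the others by Dixon's test, which flags about 1 in 20 groups by chance. Of these, 8 were ctrl10 and 5 were LKO13. Total normalized signal stood apart at 52.9 M (mega) in ctrl10 and 46.6 M in LKO13, as did the 68.6 M reads of LKO13. In ctrl10 normalized counts stood apart at peaks assigned to Gm13090 (1205 at 151414903 and 579 at 151418415), Hnrnpu (856), Gbp10 (633), Gpc1 (1447), Cntnap1 (193) and Pklr (82.3). In LKO13 they stood apart at Hoxc4 (1248), Slc17a8 (294) and Pex11a (1403). The other libraries that stood apart were ctrl9 at the shorter Lrtm2 peak (33.5), ctrl16 at Bhmt (40.9) and LKO2 at the Gm13090 peak from 151418415 (154).

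Few ATAC peaks passed with groups alone. Unequal signal between libraries is a candidate cause: without ctrl10 and LKO13 limma called 25 peaks against 5 with all libraries, and the 5 were among the 25. At least 5 calls came from 3 of 100 splits of the 12 libraries, the real grouping among them, a share under 0.05. The other 2 of these splits gave more, 5068 and 8 calls, so chance is not excluded for the count of 5. Both gave 0 calls with total signal as a covariate. Such counts point to a structure of the samples other than the genotype. With total signal as a covariate 1 of 100 splits, the real grouping, gave 58 calls, the highest other 13, which argues against chance in that fit. The splits were drawn from 462 possible, and 1 of 100 is the smallest share they can give. The covariate was chosen after the data were seen, and what made total signal differ (tissue, nuclei or library preparation) stays open.

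Macrophage and interferon genes lay higher in LKO liver RNA. All 22 measured macrophage markers had a mean of at least 10 in control livers, and 0 of them are in another list. Among abundant macrophage markers, Mpeg1 measured 3340 in controls and 5310 in LKO livers and Cd5l 2403 and 4042. Fewer hepatocytes would raise the markers of other cell types alike. In these samples the sinusoidal endothelial markers did not rise with the macrophage markers (endothelial median -0.18). The macrophage median exceeded the endothelial median by 0.715 (gene permutation p = 0.00014), and the hepatocyte identity median was 0.17. The camera shift of endothelial markers ended without LKO 1 (adjusted p = 0.114) and that of hepatocyte identity without LKO 3 (adjusted p = 0.0871). In ATAC with groups alone, hepatocyte identity gene ends were lower than random lists. For interferon genes following the macrophage share alone, the interferon median exceeded the macrophage median by 0.608 (gene permutation p = 0.00226). Gene permutation takes genes as independent, while the estimated correlation was 0.64 in the interferon list and 0.55 in the macrophage list. It does not measure the spread between livers, so neither p-value decides for or against these explanations. More macrophages in LKO livers stays open: macrophage gene ends had a median accessibility change of 0.08 against 0.01 in random lists (value 0.0801, adjusted p = 0.481), and with the signal covariate 0.12 against 0.01 (adjusted p = 0.0482). Induction within resident cells by the knockout also stays open, untested.

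Accessibility and expression changed in the same direction across genes. Of 100 splits of the ATAC libraries 1, the real grouping, gave a rho as large in size (0.227), a share under 0.05. The highest of the others was 0.209, so chance in the ATAC grouping is argued against by a narrow margin. The RNA fold changes were held at the real grouping in every split, so chance in the RNA grouping was not assessed. With total signal as a covariate rho was 0.183 (permutation p = 1e-04, the smallest those permutations give). That permutation takes genes as independent, and the splits were not rerun for rho with the covariate. Without it another split reached 0.209, so whether unequal signal is the whole cause stays open. A difference in cell types between the groups, which would move both assays together, may add to rho = 0.227 and was not tested.

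For the ATAC gene lists chance cannot be excluded: 53 of 100 splits gave at least the 11 shifted lists of the real grouping, and the highest other gave 18. For the RNA calls the 10 splits of the 5 libraries are too few for a share under 0.05; the real grouping gave 30 calls and the highest other 1.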

How the results depend on the processing

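The RNA count (30) was 19 with a mean of at least 50, 3 at adjusted p under 0.01, 253 at 0.1, 4 with Bonferroni, 0 without the mean-variance trend, and 410 with DESeq2 and in the authors' deposited table. Leaving out single libraries gave 1 (LKO 2) to 50 (LKO 1) calls, with 3 without control 2, where a lone control is assumed to vary like the LKO samples. The trend and the minimum mean were chosen with these counts in view; the cause of the difference from DESeq2 was not tested. The other RNA settings stayed within 1.5 times. With the replicate number as a block the count was 40, 16 of them among the 30. LKO 3 shares its number with no control, so it adds nothing to the group difference in that fit. Same-numbered samples had correlations of 0.062 and -0.288. With 2 controls, their deviations from the group mean mirror each other, so this check cannot tell whether numbers pair the samples. Of the lists, the block added NRF2 targets, cholangiocyte markers, the unfolded protein response and male-high genes and ended hepatocyte identity (adjusted p = 0.257). The planned ATAC block was not run, because 8 of the 12 ATAC columns carry numbers outside those of the sample titles.

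The ATAC count (5) was 2 at adjusted p under 0.01, 10 at 0.1, and 2 (without ctrl15) to 10 (without LKO13) with single libraries left out, 8 without ctrl10 and 3 without LKO11. Alternatives chosen after seeing the data gave 161 with DESeq2, 1427 in the authors' deposited table, 23 with quantile normalization and 25 without ctrl10 and LKO13. Total signal as a covariate gave 58 in limma, 67 in edgeR and 917 in DESeq2. The main within-group principal component gave 548, 476 and 3411, but it is computed from the group labels and removes spread within groups without counting it, so these are not taken as calls. The share of higher calls was 60% of the 5 limma calls, but 18.01% of the 161 DESeq2 calls from the same groups alone, 20% without ctrl10 and LKO13, 21.7% with quantile normalization and 27.6% with the signal covariate in limma, so a low share does not need the covariate. The cause was not tested.

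RNA lists (13) numbered 0 with an estimated correlation, 0 with fry's test of a single direction (its mixed test passed for 4), 23 against matched random lists and 25 against unmatched. ATAC lists (11) ranged from 5 (without ctrl10) to 13 (without ctrl16) with single libraries left out. The overlap of higher calls (1) was 0 without RNA LKO 2, 2 with the covariate (Apol9a and Lrtm2) and 23 with the authors' deposited calls (22 within 10 kb). That of lower calls (0) was 22 with the authors' deposited calls (20 within 10 kb), 3 with the covariate, 3 without ctrl10 and LKO13, 1 without RNA LKO 3 and 1 without ctrl10. The share of lower peaks at gene ends (50%) was 33.3% with the covariate (Fisher's exact p = 0.0294) and 45% without ctrl10 and LKO13 (Fisher's exact p = 0.00770). Of the values for named genes, 431 kept direction and side of the threshold in RNA, 131 dropped below it and 30 rose past it. For the 5 peaks with the smallest p in each direction these were 234, 11 and 55. None reversed. RNA depth was even between libraries; whether depth or the number of samples limits the RNA calls was not tested.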

Other observations

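The tests of crowded regions and of neighbouring genes were chosen only after the result was seen. The same rule for named genes applied to the calls of the authors' deposited table, a choice made after values were seen, brings up genes that limma did not call. Single genes called lower in LKO livers in the authors' deposited table, picked from several lists and not tested as a group, included Cidea, a lipid droplet protein gene, at -2.23, Gpam at -0.84, Apoa4 at -0.81, Elovl6 at -0.60, Acaca at -0.39, Cpt1a at -0.35 and Ppara at -0.34. Single genes called higher in the authors' deposited table included the metallothionein gene Mt2 (2.17), the glutathione transferase genes Gsta2 (2.03) and Gstm3 (1.57), and the heme oxygenase gene Hmox1 (0.64). Among cell death genes of the authors' deposited table Casp1 (1.23) and Mlkl (0.96) were higher. Of the lipid-associated macrophage list, genes called higher in the authors' deposited table included Trem2 (0.94), Lgals3 (0.81) and Mmp12 (0.76). The major urinary protein genes went apart in the authors' deposited table, with Mup20 at 1.41 and Mup3 at -0.71, though reads are hard to place among these near-identical copies. In limma the adjusted p of these genes lay above 0.05.

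A hypothesis is that long genes lost expression in LKO livers. Within deciles of mean expression, gene span and RNA log2 fold change had a rho of -0.225 over 13164 genes, the most negative of the 10 splits of the 5 libraries (next -0.176). The splits are too few for a share under 0.05, so this may also reflect RNA quality or sample structure, and it was not followed further.

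A further hypothesis is that accessibility changed by region. Of 1207 windows of 2 Mb, 24 held an excess of calls of the authors' deposited table in the same direction, against at most 2 in 1000 shuffles, so calls crowd more than single peaks placed at random; neighbouring peaks are not independent, which may account for part of it. The windows with the smallest p for higher peaks lay on chromosome 14 from 20 to 22 Mb (20 of 308 peaks called higher), chromosome 6 from 90 to 92 Mb (13 of 198) and chromosome 6 from 22 to 24 Mb (9 of 88). For lower peaks they lay on chromosome 8 from 46 to 48 Mb (15 of 177) and chromosome 5 from 74 to 76 Mb (12 of 128). The window from 118 to 120 Mb on chromosome 6, which holds Lrtm2, had 6 of 105 peaks called higher.

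A hypothesis that neighbouring genes changed together in RNA did not meet its rule, a count above every shuffle also with families left out. Missing so strict a rule does not reject the hypothesis. Of the genes called in the authors' deposited table, 76 had a called neighbour of the same direction within 100 kb, above the 48 of any shuffle. With families left out by the opening letters of their names 38 did, within the range of the shuffles (median 25, highest 48). This rule missed families with short names, so the pairs Mx1 with Mx2 and Mt1 with Mt2 stayed in.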
